A study of Drosophila melanogaster with 2 samples.

How the data were processed

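The samples were 2 biological replicates of mixed-sex whole embryos aged 0 to 16 h from a line that expresses Jing fused to GFP, precipitated with an antibody against GFP after sonication to 200 to 800 bp, per the labels. Per the file headers of the readme text deposited with each sample, peaks of each replicate and of the pooled reads were called against a control alignment on dm6, and the thresholded list was derived from the replicate lists and the pooled list by the irreproducible discovery rate step. The aligner, the peak caller and their versions are not given in the sources used here. The control was not analysed here. On Y there were 2 relaxed peaks, both in replicate 3. Each deposited peak has a signal value whose scale is not given, and the −log10 of a q-value by the definition of the narrowPeak format. Signals were used only for ranks and descriptions, and between lists only for ranks, a correlation across peaks and its median ratio.

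The thresholded list was tested against the pooled list and held exactly its 2593 strongest peaks by signal. The lowest −log10 q-value in the deposited thresholded list was 2.01, a level reached by 3185 peaks in replicate 2 and 2002 in replicate 3. The deposited relaxed lists stop at 30000 peaks, so their lengths say nothing on how much was bound. The depth of each library is unknown, and Wilson, Poisson and binomial intervals at 95% cover counting error only. They treat peaks as independent, which neighbouring peaks are not. With 2 replicates of 1 group there is no test between samples, and p-values describe positions, genes or sequences within the peak lists.

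Genes came from Ensembl release 115 and sequence from the Release 6 assembly, whose arm lengths matched the lists. Summits were classed in the order promoter (within 500 bp of any of 23694 start sites), 5' UTR, 3' UTR, coding exon, non-coding exon, intron and intergenic, and compared with 1000 random placements on the same arm. A gene had a peak when a summit lay in its span or within 1 kb. The 20 gene lists, with 382 names of which 14 were matched through older symbols, were compared with 100000 draws of other genes of the same class and decile of span length. The 21 consensus sequences and all 6-mers were compared between the 200 bp around the summit and 200 bp centred 500 bp away by an exact paired test. All tests were two-sided. Those of the annotation classes against random placements, the gene lists, the consensus sequences and the 6-mers were Benjamini-Hochberg adjusted within their family. Only p-values called adjusted carry this correction. The others are unadjusted, except where a Bonferroni correction is named. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

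Lists, sequences, tests and the rule for named genes were fixed before the data were examined. The rule takes the 15 strongest peaks with the gene of the nearest start site, at most 5 peaks in the jing locus, the 4 members with the strongest peak of each list that passed 0.05 and up to 2 of each that did not. Genes with the most peaks, RpS3A and the genes near peaks missing from the thresholded list were named after their values were seen. Alternatives fixed then were the 1296 strongest peaks, each replicate left out in turn, merging of summits within 200 bp, other distances and windows, start sites of protein-coding genes, other rules that assign genes to peaks and a test without matching. Added after seeing the data were the pooled peaks below the threshold as background, matching on the number of start sites, and shuffled summits. Replicates left out means the 2593 strongest peaks of the other replicate alone.

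The steps were tested on simulated data. In 2500 simulated peaks with 500 planted at start sites, the promoter share was 31.1%. The share expected from planted and random peaks together was 30.8%. With none planted it was 13.9%. Of 100 simulated lists of 30 genes with 12 given a peak, 100% passed 0.05, and 3% of lists with none added did. A sequence planted in 250 of 2500 windows raised the share of matches by 9.76 points. That rise follows from the planting itself, so it shows only that the search finds the sequence. Simulated lists held genes taken at random, with peaks given regardless of gene length. They thus did not test the length matching or lists of neighbouring genes.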

Results

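The data came from chromatin immunoprecipitation followed by sequencing (ChIP-seq) on whole Drosophila melanogaster embryos of mixed sex, collected at 0 to 16 h. The embryos carried Jing, a zinc finger protein with known roles in tracheal and central nervous system midline development, fused at its C terminus to green fluorescent protein (GFP), and an antibody against GFP was used. There was 1 group of 2 biological replicates, numbered 2 and 3 in the labels and taken from separate biosamples, so no comparison between groups was possible. The question the design addresses is where the tagged protein was found along the genome and how alike the replicates were. Each replicate had a list of 30000 relaxed peaks, the pooled reads had a further list of 30000, and a list of 2593 thresholded peaks had been derived from these. The depth of the libraries is unknown, because the peak lists hold no counts. Coordinates are in dm6 and 1-based.

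Of the 15 strongest thresholded peaks, 12 lay at promoters and 3 in introns, and they were spread over the arms. Positions relative to a start site are negative upstream of it. The highest signal, 2208, was at arm 3L 19590615 (peak 19590456 to 19590771), at -91 bp from the start site of CG14100 and within 1 kb of the 3' end of ash1, which encodes a Trithorax group histone methyltransferase. It was followed by a peak at -36 bp from the start site of Ugalt, a UDP-galactose transporter gene, at X 2703888 with a signal of 2151. The next was at -492 bp from a start site of ph-p, a Polycomb repressive complex gene, at X 2137347 with a signal of 1947. The fourth lay in an intron of ush, with cbt as the gene of the nearest start site, at 2L 481091 with a signal of 1778. The fifth was at -192 bp from the start site of px, at 2R 22514291 with a signal of 1742. The other 10 of the 15 strongest peaks were nearest to CG11050, Chro, CG1888, Lk6, PNPase, CenG1A, Art3, CG9147, Tcs5 and CG31145, with signals from 1613 down to 1222. Of Chro, which encodes a chromodomain protein, the summit was at 3L 22878910, 74 bp downstream of the start site. The signal is the authors' own value for a peak and is used here only to rank and describe peaks. Thresholded peaks had signals from 106 to 2208 with a median of 170, and a median width of 364 bp.

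The replicates placed their strongest peaks at many of the same positions. The peaks near CG14100, Ugalt and ph-p took ranks 2, 4 and 1 in replicate 2 and ranks 2, 1 and 3 in replicate 3. Among the 2593 strongest peaks of each replicate, 1805 of replicate 2 (69.6%, 95% Wilson interval 67.8 to 71.4) had a summit of replicate 3 within 100 bp. When 1 list was shifted along each arm, the mean share was 0.376% and the highest of 100 shifts was 0.656% (permutation p = 0.0198, two-sided, the smallest that 100 shifts can give). Of the thresholded peaks, 2532 were in the relaxed list of replicate 2, 2498 in that of replicate 3 and 2440 in both. Across these 2440 peaks, which are not independent replicates, Spearman's rho of the signals was 0.669 (bootstrap interval 0.643 to 0.694) and Pearson's r of log10 signal was 0.758. Some genes differed strongly in rank: the peak at -45 bp from the start site of gcm, the glial determinant, was at rank 281 in replicate 2 and 5912 in replicate 3.

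**Figure D1:**
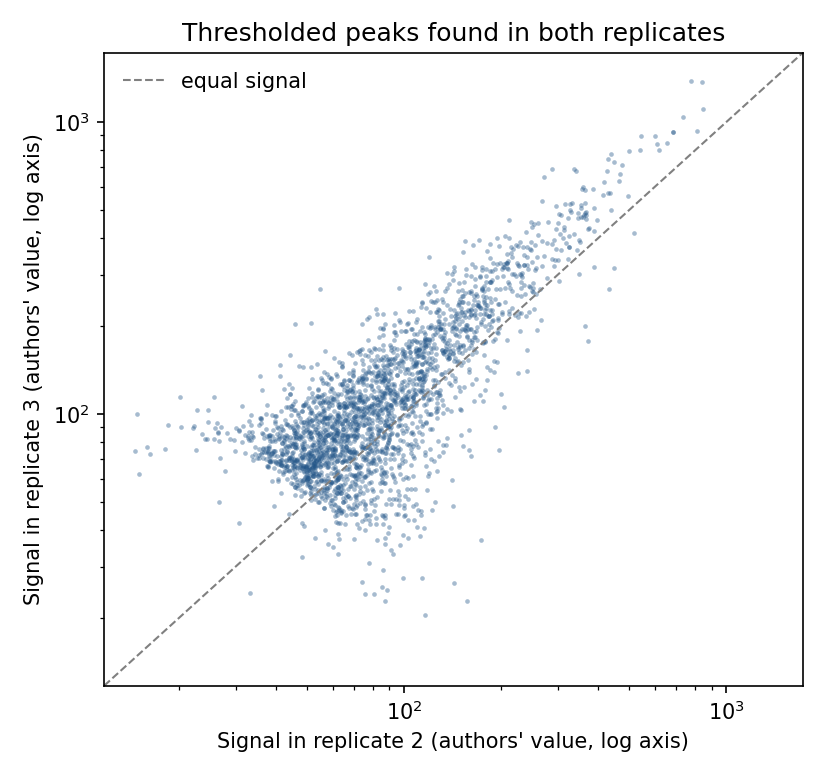
Signal of the 2440 thresholded peaks found in both replicates, replicate 2 on the x axis and replicate 3 on the y axis, both log axes in the authors' signal values; each point is 1 peak and the dashed line marks equal signal. The points rise together (rho 0.669) and lie mostly above the line, with a median ratio of replicate 3 to replicate 2 of 1.34.

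Promoters held more thresholded summits than random positions did, and coding exons held almost none. Within 500 bp of an annotated start site lay 1059 of 2593 summits (40.8%, 95% Wilson interval 39.0 to 42.7), against a mean of 13.6% for random positions on the same arms, which is 3.01-fold more. Coding exons held 5 summits (0.193%), 68.0-fold below the random mean of 13.1%, and 3' UTRs held 13 (0.501%) against 5.06%. Intergenic positions took 17.5% against 27.1%. These differences had an adjusted permutation p of 0.0035 over 7 classes, from a raw p of 0.0020, the smallest that 1000 placements can give. Introns held 1019 summits (39.3%), which did not differ from the random mean of 39.5% (permutation p = 0.869). The 5' UTRs held 10 summits (0.386% against 0.776%, adjusted permutation p = 0.0252) and non-coding exons 32 (1.23% against 0.813%, adjusted permutation p = 0.0396).

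The promoter share followed the strength of the peaks. It was 54.0% (95% Wilson interval 50.2 to 57.8) in the 648 strongest thresholded peaks, 41.0% and 37.7% in the next sets of 648 and 30.7% (27.2 to 34.3) in the weakest 649. Promoter summits lay mainly upstream of the start site: the median position was -134 bp, with quartiles of -236 and -38 bp, and 220 of 1059 (20.8%) were downstream. Among the 27407 pooled peaks below the threshold, a background chosen after seeing the data, the promoter share was 15.3% (odds ratio 3.82, Fisher's exact p = 1.01e-190). Against these peaks introns were less frequent in the thresholded list (39.3% against 44.2%, odds ratio 0.818, Fisher's exact p = 1.53e-06), and non-coding exons did not differ (1.23% against 1.05%, Fisher's exact p = 0.368).

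**Figure D2:**
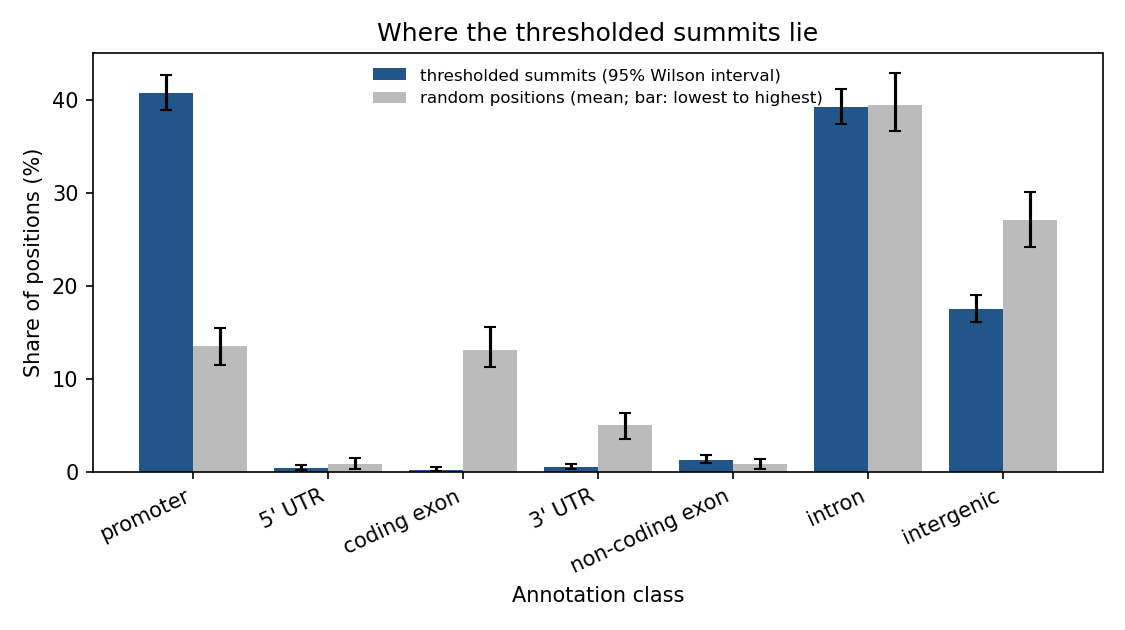
Share of positions (%, y axis) in each annotation class (x axis) for the 2593 thresholded summits, with 95% Wilson intervals, and for 1000 random placements on the same arms, with bars from the lowest to the highest placement. Promoters stand at 40.8% against 13.6%, and coding exons at 0.193% against 13.1%.

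Peak density on the X lay within the range of the large autosomal arms, which differed among themselves. There were 22.0 thresholded peaks per Mb on 2L (exact Poisson interval 20.1 to 24.0), 17.0 on 2R (15.4 to 18.7), 19.8 on 3L, 18.3 on 3R and 20.8 on X. The small arm 4 held 14 peaks, 10.5 per Mb (exact Poisson interval 5.75 to 17.6), with summits at -123 bp from the start site of toy, an eye determination gene, at 4 989602 and at -136 bp from that of RpS3A at 4 67343. On Y there was none, which allows up to 0.880 per Mb by a limit of 3 counts, or 1.08 by the exact Poisson interval. Both limits assume that peaks on Y could be called. The relaxed pooled list also held none there, against 157 per Mb below the threshold on X, so the limits do not bound binding on Y. The ratio of X to the 4 large autosomal arms was 1.08 (95% interval 0.981 to 1.20, exact binomial p = 0.110, two-sided). With replicate 3 alone the ratio was 1.14 (exact binomial p = 0.00999), and with replicate 2 alone it was 0.959 (exact binomial p = 0.439). In the 1296 strongest peaks it was 1.15 (exact binomial p = 0.0452), and relative to the peaks below the threshold the odds ratio was 1.49 (Fisher's exact p = 3.83e-13). In embryos of mixed sex the X is present in fewer copies than the autosomes, which these ratios do not take into account.

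Several long genes held many peaks, counts that were not tested against gene length. Of 18277 annotated genes, 2405 had a thresholded summit in the gene or within 1 kb, 2090 of them among the 13968 protein-coding genes. The most were in lncRNA:CR44357 with 16 peaks and in CG1677, which it overlaps on X, with 14. The Friend of GATA gene ush had 12, the myoblast fusion gene kirre 11, the kinase gene Raf 10, and the ecdysone-induced receptor gene Eip75B and the corepressor gene sbb 9 each. In all, 42 genes had 5 or more.

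The jing gene itself, FBgn0086655 at 2R 6502006 to 6621792 on the plus strand, held 8 thresholded peaks. The strongest had its summit at 6501966, at -40 bp from the start site, with a signal of 924, and was at rank 35 of all thresholded peaks. The next lay in introns, at 6595407 with a signal of 235, at 6606081 with 142, at 6607679 with 134 and at 6524277 with 118. The gene with 20 kb on both sides (2R 6482006 to 6641792) held 90 summits of the relaxed pooled list, against a mean of 31.5 in 1000 random windows of that width on the arm (2.86-fold, permutation p = 0.024, two-sided). For the 8 thresholded peaks the random mean was 2.72 (permutation p = 0.142), and with 50 kb on both sides the ratio of relaxed summits was 2.09 (permutation p = 0.0959). The counts depended on the replicate: replicate 2 alone gave 125 relaxed summits, 11 of them from its 2593 strongest peaks (permutation p = 0.018 and 0.038), and replicate 3 alone gave 68 and 6 (permutation p = 0.032 and 0.316). Of the 1296 strongest peaks the locus held 2 against 1.40 (permutation p = 0.703). The line expresses jing from a transgene, and its number of copies of the locus is not given in the sources used here.

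**Figure D3:**
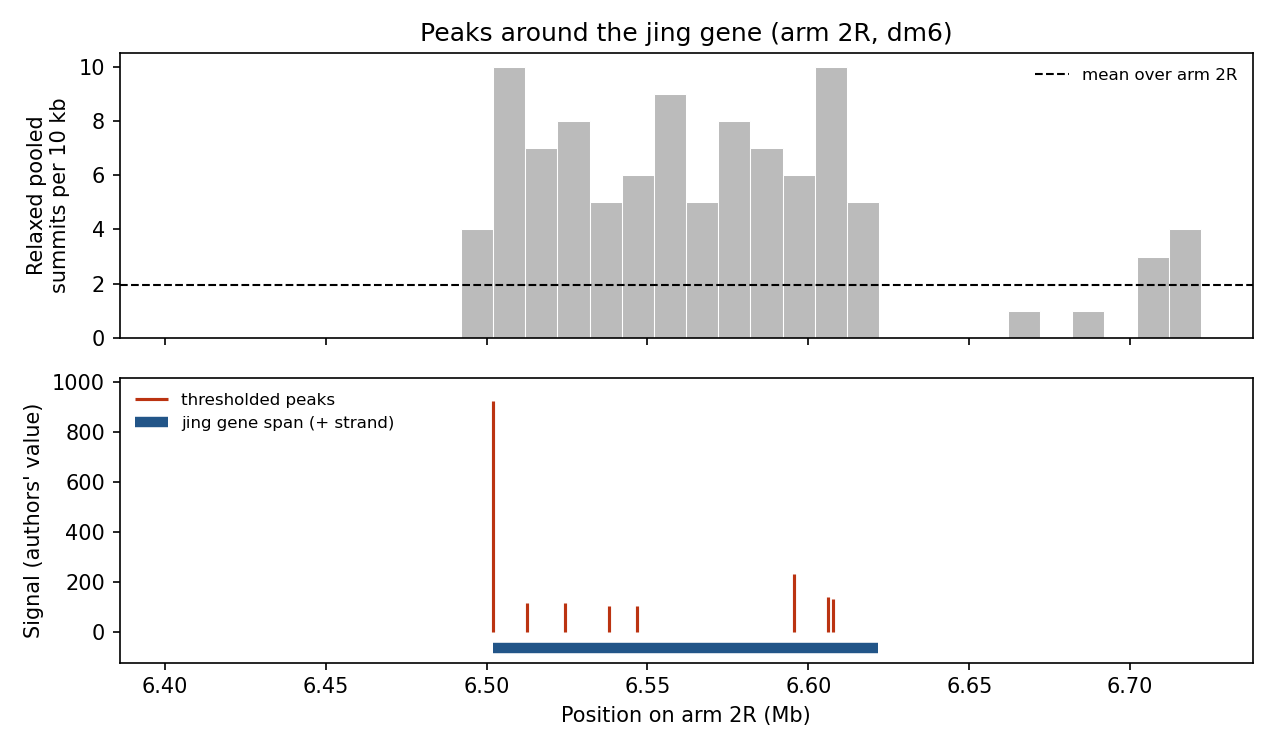
Map of the jing gene on arm 2R (x axis, position in Mb, dm6): above, relaxed pooled summits per 10 kb with the arm's mean as a dashed line; below, the 8 thresholded peaks by the authors' signal, with the gene span as a bar. Relaxed summits fill the gene span, and the thresholded peak with a signal of 924 stands at its start site.

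Ribosomal protein genes carried peaks more often than other genes of their length. Of 92 such genes, 29 had a thresholded summit, against a mean of 7.19 (central 95% of draws 3 to 13) for genes matched on span length (4.03-fold, adjusted permutation p = 0.0004 over 20 lists, from a raw p of 2e-05, the smallest that 100000 draws can give). The strongest were at RpS27, at -14 bp from the start site at 3R 25247528 with a signal of 517, at RpL23A (3L 1668771, signal 396), at RpL7 (2L 10201021, signal 379) and at RpL14 (3L 8600978, signal 314). Of the 33 peaks in or near these genes, 32 were at promoters. With replicate 3 alone 20 genes had a peak (2.60-fold, adjusted permutation p = 0.0016), and with replicate 2 alone 44 had one (5.67-fold, adjusted permutation p = 0.0002). With matching also on the number of start sites, chosen after seeing the data, the ratio was 2.64 (adjusted permutation p = 0.0004).

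Genes of midline cells and glia, which include tissues in which Jing is known to act, carried peaks in 18 of 27 cases against 8.40 (central 95% of draws 4 to 13) for matched genes (2.14-fold, adjusted permutation p = 0.0014). The ETS factor gene pnt had its strongest peak at -269 bp from a start site, at 3R 23295507 with a signal of 763. The others with the strongest peaks were aos, an Egfr antagonist gene, in an intron at 3L 16480578 (signal 668), spi, an Egfr ligand gene, at 2L 19575789 (signal 611), and moody, a blood-brain barrier receptor gene, at X 2050278 (signal 547). The list shares pnt, rho, Egfr and btl with that of tracheal genes, which did not pass. Segmentation (1.68-fold) and muscle genes (1.54-fold) also had ratios above 1 without passing. Hox, differentiated neuron, haemocyte and fat body, germline and transfer RNA genes had ratios below 1.

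Polycomb and Trithorax components had peaks in 15 of 33 cases against 7.49 (central 95% of draws 3 to 12; 2.00-fold, adjusted permutation p = 0.0303). The strongest was counted for ash1, although its summit lies beyond the 3' end of that gene and at the promoter of CG14100. It was followed by ph-p and by Trl, the GAGA factor gene, in an intron at 3L 14759521 with a signal of 944, and jing itself. The list thus counts the tagged gene among its 15. These also include the neighbouring genes ph-p and ph-d, and Psc and Su(z)2, whereas the draws treat genes as independent. With 1 replicate left out the call was lost: 14 genes had a peak in either case, 1.82-fold without replicate 2 (adjusted permutation p = 0.0736) and 1.83-fold without replicate 3 (adjusted permutation p = 0.0503).

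The replication-dependent histone genes had no peak in any of 111 copies, against a mean of 5.47 for matched genes. These copies form 1 repeated cluster on 2L and are not independent, so the draws of scattered genes give no test of the difference. How reads in repeats were treated is not given in the sources used here.

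The other 16 lists did not pass the test. The Polycomb target regulators outside the Hox clusters had peaks in 23 of 52 cases against 14.8 (1.56-fold, adjusted permutation p = 0.0562), with wg (2L 7307006, signal 567) and toy the strongest. That list rested on replicate 2, which alone gave 35 genes (2.38-fold, adjusted permutation p = 0.0002), while replicate 3 alone gave 17 (1.14-fold, adjusted permutation p = 0.710). It also passed with summits within 1 kb of a start site (2.09-fold, adjusted permutation p = 0.016), by the nearest start site (2.20-fold) and with matching on start sites, chosen after seeing the data (1.84-fold, adjusted permutation p = 0.0066). Of the 8 Hox genes, Antp and lab had a peak, against 3.47 for matched genes, with signals of 168 and 156. Tracheal genes had peaks in 16 of 30 cases against 10.3 (adjusted permutation p = 0.0967), with pnt and heca the strongest, and passed when each peak was given to the gene of the nearest start site (15 against 8.01, 1.87-fold, adjusted permutation p = 0.0247). Border cell, JAK/STAT and ecdysone genes had them in 14 of 24 against 8.38 (adjusted permutation p = 0.0715), led by Hr3 with a signal of 657 and Hr4 with 532. Differentiated neuron genes had them in 2 of 18, elav and ChAT, against 6.74 (adjusted permutation p = 0.0715, or 0.0456 with matching on start sites).

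Segmentation genes had peaks in 8 of 23 cases, with wg and ftz-f1 the strongest, neural progenitor genes in 8 of 24, with brat and grh, and muscle genes in 10 of 21, with sls and mbc. Segmentation genes passed by the nearest start site (2.51-fold, adjusted permutation p = 0.0247) and with replicate 2 alone (2.49-fold, adjusted permutation p = 0.0054), as in the latter case did appendage genes (1.71-fold, adjusted permutation p = 0.0498). Appendage genes had them in 12 of 24, with wg and Lim1, and signalling genes in 12 of 29, with spi and wg. Gut genes had them in 5 of 13, with bowl and Hnf4, epidermis and cuticle genes in 5 of 14, with grh and sn, and haemocyte and fat body genes in 3 of 16, with ush and gcm. Of 13 germline genes none had a peak, against 2.67 for matched genes (adjusted permutation p = 0.189). Transfer RNA genes had peaks in 9 of 295 cases (0.804-fold), with tRNA:Tyr-GTA-1-8 the strongest, and when each peak was given to the gene of the nearest start site the ratio turned to 2.94. Many of these genes lie side by side, and the draws treat them as independent. Small nuclear RNA genes had them in 2 of 32. Without matching on length, 12 of the 20 lists passed with more genes with a peak and 2 with fewer (Fisher's exact test).

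**Figure D4:**
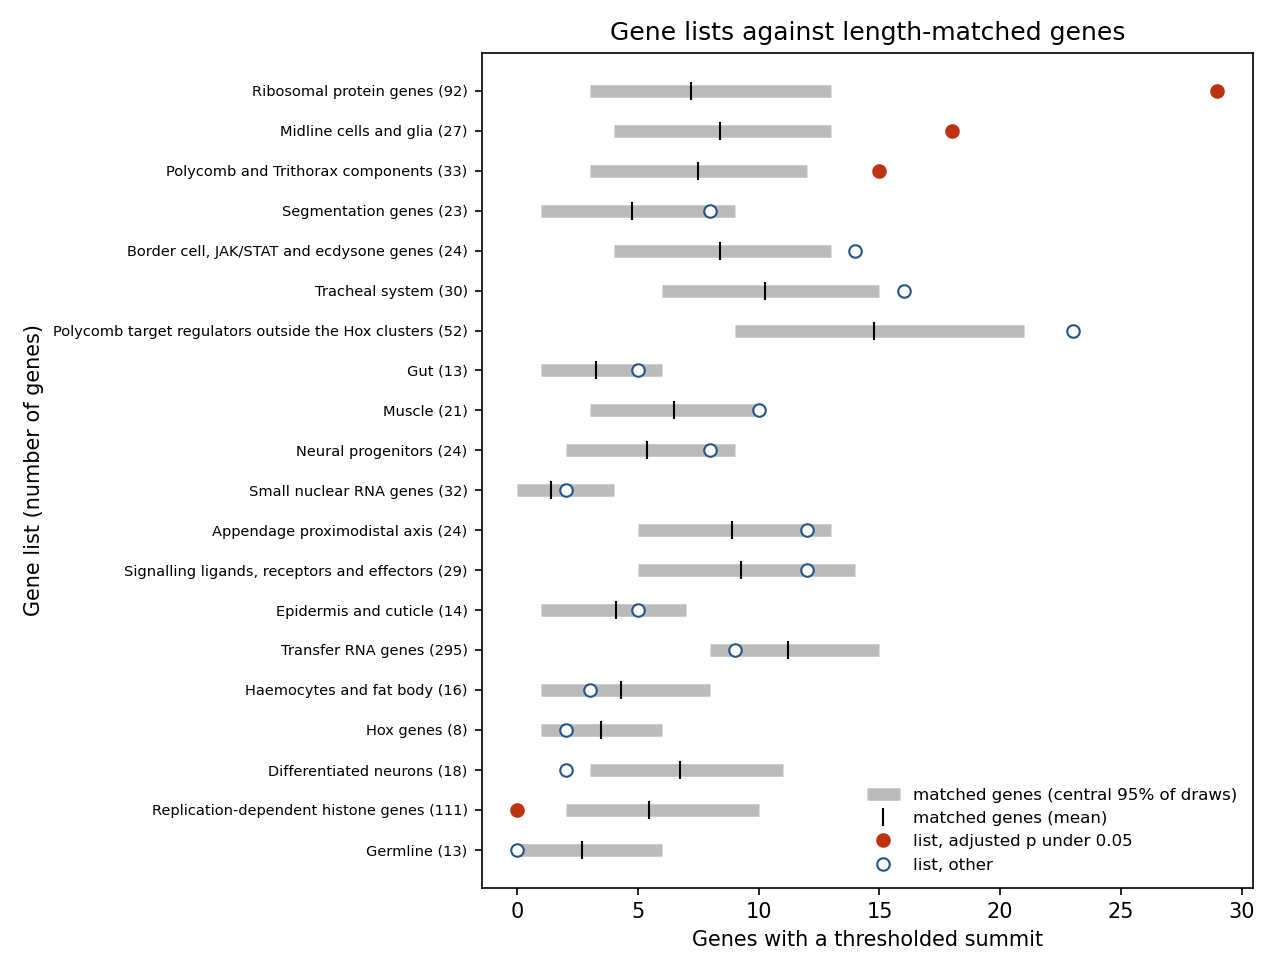
Number of genes with a thresholded summit (x axis) in each of the 20 gene lists (y axis, list size in brackets); points are the lists, filled where the adjusted p was under 0.05, ticks the mean and grey bars the central 95% of draws of length-matched genes. Ribosomal protein genes stand at 29 against 7.19, midline and glial genes at 18 against 8.40, and histone genes at 0 against 5.47, a list of adjacent copies for which the draws give no test.

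Summits were richer in A and T than their flanks, and MEF2, Su(Hw) and DRE sequences were among those more frequent at them. The GC content of the 200 bp around the summit was 35.9% ± 7.23 (SD over 2593 peaks) and that of windows 500 bp away was 42.9% ± 8.54, and it was lower at the summit in 1934 peaks (74.6%). Of 21 consensus sequences, 6 were more frequent at summits and 4 less. The MEF2 consensus matched in 295 summits against 162 flanks (1.82-fold, adjusted exact p = 9.22e-10), Su(Hw) in 38 against 14 (2.71-fold, adjusted exact p = 0.00502) and DRE, bound by DREF and BEAF-32, in 28 against 10 (2.80-fold, adjusted exact p = 0.0119). The homeodomain (1.28-fold), GATA (1.20-fold) and initiator (1.11-fold) sequences were also more frequent. The GT repeat bound by Combgap was less frequent (75 against 181, 0.414-fold, adjusted exact p = 7.45e-11), though less so with replicate 2 alone (114 against 173, 0.659-fold). The Spps/KLF (0.684-fold) and Snail/E-box (0.735-fold) sequences were also less frequent. The AP-1 call (0.600-fold, adjusted exact p = 0.0219) was lost in each of the 7 alternatives, with ratios of 0.600 to 1. The GAGA repeat matched 4.44% of summits and 5.63% of flanks (adjusted exact p = 0.103), and the Pho consensus 5.40% and 5.86% (adjusted exact p = 0.663). The GAGA ratio depended on the replicate, at 0.574 with replicate 3 alone (adjusted exact p = 6.67e-05) and 1.05 with replicate 2 alone (adjusted exact p = 0.741). It was also called lower in the 1296 strongest peaks (0.607, adjusted exact p = 0.0169) and in 100 bp windows (0.594, adjusted exact p = 0.0238).

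These calls depended on the setting. In the 1296 strongest peaks, and with flanks 1 kb away, MEF2 and Su(Hw) kept their call among the more frequent sequences and the GT repeat and Spps/KLF among the less frequent, while DRE stayed at 2.33-fold and 2.00-fold without passing (adjusted exact p = 0.242 and 0.183) and fell to 1.67-fold in 100 bp windows (10 against 6, adjusted exact p = 0.561). The Su(Hw) call was lost with replicate 2 alone (1.94-fold, adjusted exact p = 0.069) and in 100 bp windows (1.89-fold, adjusted exact p = 0.272). Against dinucleotide-shuffled summits, chosen after seeing the data, DRE (5.60-fold, adjusted exact p = 0.000278), Su(Hw) (2.00-fold, adjusted exact p = 0.0364) and MEF2 (1.24-fold, adjusted exact p = 0.0229) kept their call. The initiator lost its call (1.05-fold, adjusted exact p = 0.202), and M1BP (12-fold, 12 against 1), CTCF (3.71-fold, adjusted exact p = 3.59e-14) and the Twist E-box (1.42-fold, adjusted exact p = 0.00441) gained one. Flanks were not shuffled, so a call against shuffled summits does not set summits apart from other genomic sequence. CTCF matched 130 summits, 123 flanks and 35 shuffled summits, and the GT repeat 75, 181 and 18. Against flanks the Twist E-box was also called more frequent with replicate 3 alone (1.30-fold, adjusted exact p = 0.0174) and with replicate 2 alone (1.34-fold, adjusted exact p = 0.0194). Among sequences called against either background, the homeodomain (0.845, called less frequent with an adjusted exact p of 0.0364) and GATA (0.959) ratios fell below 1, while the GAGA repeat (4.79), the GT repeat (4.17) and the Snail/E-box sequence (2.20) rose above it. Of all 6-mers, each counted with its reverse complement, 466 were more frequent at summits than in flanks and 858 less, and 87.3% of the former held at most 2 G or C bases. Among 6-mers in at least 5% of summits, the highest ratios were those of AGTGTA (473 summits against 173 flanks, 2.73-fold), GTGCAC (2.59-fold), CTAGTA (2.51-fold) and ACACTG (2.34-fold). Against shuffled summits GTGCAC was at 3.64-fold, ACAGTG at 2.43-fold and ACACTG at 2.16-fold, whereas CTAGTA was at 0.812.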

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

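Tests chosen only after a result was seen were the matching on the number of start sites and the comparison of jing with other long genes. Among the 2593 strongest peaks of both replicates, 21 shared positions had no thresholded summit within 100 bp, a signal in the replicate lists that the comparisons left unused. What number to expect was not tested. Of these, 19 had no summit in the relaxed pooled list within 100 bp either, and 15 lay over 500 bp from any thresholded summit. The strongest in replicate 2 was at X 19850684, at -634 bp from the start site of pico, with a signal of 174 and rank 282. Others lay near spidey (X 7908720, rank 507) and CG4658 (2L 9957157, rank 643).

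The relaxed pooled list held 86 summits in the jing gene, 7.18 per 10 kb against 1.96 over arm 2R. They were spread over the gene, with 30, 28 and 28 in successive parts of equal length, 4 in the 20 kb upstream and 0 in the 20 kb downstream. Extra copies of the locus in the tagged line may contribute. Away from start sites the locus held 83 summits, more than 98.9% of random windows on the arm. These windows were matched on width only, so the value cannot tell extra copies from a gene dense in peaks. Among 313 genes of at least 50 kb jing was at rank 3, after pnt (9.12 per 10 kb) and Eip75B (7.30), which were not tagged, so such a density also occurs without a tag; this does not argue against extra copies at jing. Binding by Jing to its own gene was not tested apart from copy number and remains open.

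For ribosomal protein genes, closely packed start sites were tested by matching also on the number of start sites, and the ratio was 2.64 (permutation p = 2e-05, the smallest that 100000 draws can give), down from 4.03. Packing could thus account for part of the ratio. The matching used coarse groups by number of start sites, so it cannot settle whether finer differences in packing account for the rest. High transcription that draws signal whatever the antibody would make these peaks strong. Their promoter peaks had a median signal percentile of 43.0 among promoter peaks, within the central 95% of random draws (34.1 to 66.4, permutation p = 0.404). The rule written beforehand counted a median at or below the middle percentile against this reading, and the value met it. The reading was left open only after the value was seen, because that value lay within the random range. No biological explanation was tested, as the design has 1 group.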

How the results depend on the processing

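The backgrounds of shuffled summits, of peaks below the threshold and of start-site matching were chosen after the data were seen; all others were planned. The share at promoters (8 alternatives) and the agreement of replicates (6) kept their direction and their side of the threshold in each. The stricter peak set held 1296 by construction, leaving out a replicate gives no number of peaks, and merging gives no relaxed count in the jing locus. Within 50 bp rho was 0.711, where fewer peaks matched. The X to autosome ratio was 1.15 in the 1296 strongest peaks, 0.959 to 1.14 with a replicate left out, and 1.49 against peaks below the threshold. Lists with more peak-bearing genes numbered 7 by nearest start site, 12 without length matching, and 2 to 5 with a replicate left out, against 3. Transfer RNA genes turned from 0.804 to 2.94 by nearest start site. The jing locus ratio was 2.09 with 50 kb on both sides, a window with 91 summits against 90. Sequences more frequent at summits numbered 2 in the 1296 strongest peaks, which are fewer, and 2 with flanks 1 kb away, against 6. Among sequences called against flanks or shuffled summits, the ratio crossed 1 between them for the GAGA repeat (4.79), the GT repeat (4.17), Snail/E-box (2.20), homeodomain (0.845), GATA (0.959), CTAGTA (0.812) and ATACTA (0.931), and 277 6-mers were more frequent, against 466. Of values for single gene lists, 136 stayed on their side of the threshold, 19 gained a call, 4 lost one and 1 turned; for sequences 112, 8, 22 and 5; of named 6-mers 66 stayed, 2 lost the call and 2 turned; of named peaks 142 kept their place and 8 lost it. Where no reason is given the cause was not tested. No paired analysis was possible because there was 1 group. Unknown depth limits any statement on weak or missing peaks.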

Other observations

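Tests chosen only after a result was seen were the X ratios by rank, the search for 8-mers and its rule by ratio, the test against shuffled summits, and the exclusion of peaks near thresholded summits. The tests in lower-ranked peaks as a whole and in transposable elements were also chosen after the sequence had been found, but before their own results were seen. The former replaced a split of the thresholded peaks into odd and even ranks, which was run and left out because the search had covered all of these peaks. A test of X copy number as the reason for the X ratios was also run after they were seen. Its outcome differed between lists, and it was left out.

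X and autosomal peaks differed in how they were spread over ranks. Below the threshold the pooled list had 0.727 peaks per Mb on X for each on the large autosomal arms (95% interval 0.702 to 0.753), against 1.08 above it. Outside the 2593 strongest peaks the ratio was 0.770 (0.744 to 0.796) in replicate 2 and 0.686 (0.662 to 0.711) in replicate 3, intervals that do not meet. Within them it was 0.959 and 1.14. None of these ratios takes into account that X is present in fewer copies than the autosomes in embryos of mixed sex. Annotated transposable elements held 11 thresholded summits (0.424%) and cover 5.91% of the arms. How reads in repeats were treated is not given in the sources used here, so this low share does not show less binding there.

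CACTGAGA, or its reverse complement TCTCAGTG, was in 139 of 2593 summit windows and in 11 flanks (12.6-fold, exact paired p = 1.55e-30, or 5.04e-26 after Bonferroni correction for 32558 8-mers). It ranked first both by ratio, among 8-mers in at least 2% of summits, and by the difference between summits and flanks over the root of their sum. The rule by ratio was set after the sequence had been noticed. It was more frequent outside promoters (107 of 1534 summits) than at them (32 of 1059); this difference was not tested.

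Technical readings of this sequence were tested. Chance choice would not carry over to other peaks, yet in the 2593 pooled peaks ranked next below the threshold it was in 95 summits and 27 flanks (3.52-fold, exact paired p = 1.42e-10). Without those within 1 kb of a thresholded summit, a step added after that value was seen, it was in 87 and 11 of 2343 (7.91-fold). Against shuffled summits of the same composition the ratio was 19.9. Of the 139 summits 0% lay in annotated transposable elements. These held only 11 of all 2593 thresholded summits, so a low share was given for any sequence and decides nothing on this one. Repeats stay open, and no biological explanation was tested. That the sequence may mark sites of precipitation is a hypothesis found in these same data.

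Of the 2593 summits, 2119 (81.7%) lay within 1 bp of the midpoint of their peak, so positions relative to the summit are mostly positions relative to that midpoint. The sequence occurred 56 times from -100 to -50 bp and 59 times from 50 to 100 bp, against 17 and 24 times in the 50 bp on either side. Of 4369 occurrences on the arms, 157 (3.59%) lay within 100 bp of a thresholded summit.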
